A study of Mus musculus with 9 samples.

How the data were processed

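Single-cell RNA-seq was done on non-parenchymal cells of mouse liver, the cells other than hepatocytes, which were freed by enzymes, stained with fluorescent antibodies and purified by FACS, per the labels. Each of the 9 libraries was made with the 10x Genomics 3' kit of chemistry version 2. The labels put 3 libraries, with the letters A, B and C, in each of 3 groups: control mice, mice after 2 weeks of carbon tetrachloride (CCl4), and mice after 4 weeks of CCl4. The deposited matrices held whole-number UMI counts per gene and cell barcode, 1 matrix per library, with no normalization. Reads had been processed with Cell Ranger 2.1.0 against the mouse build mm10, per the submitters' processing notes. Gene symbols and Ensembl identifiers were those deposited with the matrices, and where 2 identifiers had 1 symbol, the more expressed one kept it. Gene coordinates came from the GENCODE annotation of GRCm38, the assembly that mm10 names.

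From these counts the following was computed. Of 57761 barcodes, 55397 had at least 500 genes and at most 10% mitochondrial UMIs. Scrublet, as run within scanpy per library with an expected 6% of doublets, called 1774 cells (3.20%), which were removed. Cells were scaled to their total, log-transformed, reduced to 40 principal components of 2000 variable genes and grouped by Leiden clustering on 20 nearest neighbours at resolution 1, without any correction between libraries, into 30 clusters. Of these, 3 clusters with over 50% called doublets, 2090 cells in all, were left out. Clusters were named from marker lists when at least 3 markers of a class were detected and the leading genes did not go against the name. This gave 53071 cells, of which 12924 were stellate-like, 23797 endothelial-like and 10975 macrophage-like, and these names are used below without the suffix. The markers of the stellate class include genes of matrix-producing cells such as Col1a1, so quiescent and matrix-producing stellate cells form 1 class. Cluster 3 was named stellate with 2 stellate markers and 2 portal fibroblast markers, Mfap4 and Dpt, among its 10 leading genes. At resolution 2 a cluster of 976 cells led by Mfap4, Dpep1 and Dpt was left unnamed. Portal fibroblasts may therefore be part of the stellate class. Since names were rebuilt from markers, they can differ from those the submitters used.

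UMIs were summed per library and class, and the 9 sums of a class entered 1 quasi-likelihood fit in edgeR, with TMM normalization, its filter on low counts and no covariate. All 9 libraries shared 1 estimate of the spread. A library with under 50 cells of a class was left out of it, which applied only to 4-week library A in the main subtype of macrophages. A gene was called at a Benjamini-Hochberg adjusted p at or under 0.05 over all genes tested. Adjusted p-values of single genes are from this edgeR test unless another tool is named. Fixed lists of genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of 1 class and comparison, and again with an estimated correlation. Counts of list members are given over all genes and adjusted over the list alone. Shares of cells with a UMI were compared between libraries with a two-sided exact permutation test after each cell was thinned to 1000 UMIs. Overlaps between comparisons against the same controls were set beside 10 simulations of unchanged groups.

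The comparisons, lists, marker genes, tests and most alternatives were fixed before the data were examined. Genes were named by a rule. For each class and each CCl4 group against controls it took the 8 largest rises and the 8 largest falls among called genes with an average log2 CPM of at least 5 and no overlap between the libraries of the groups, leaving out markers of other classes. Between 4 and 2 weeks it took 5 each way. It added up to 4 members per list with the smallest adjusted p, and well-known members whatever their result. The text gives a selection of these genes, chosen after their values were seen, which mainly leaves out genes whose calls ended when single libraries were left out. Gpnmb in stellate cells and Cxcl13, Ccl24 and Marco in macrophages fell outside the rule and were chosen after their values were seen.

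On simulated counts made from the control and 2-week stellate libraries, with 200 of 11921 genes changed in each of 5 simulations, the test recovered 19.4% of genes changed 1.5-fold, 69.6% of those changed 2-fold and 91.2% of those changed 4-fold, and 6.41% of calls were false. For the same comparison the values were 32.8%, 71.9%, 93.3% and 5.86% over 11962 endothelial genes, and 9.85%, 53.7%, 87.3% and 5.65% over 11115 macrophage genes. There differences under 2-fold were often missed at 3 libraries per group. The data had far more calls at 2 weeks, so these shares may not hold. UMI totals per library and class were 1425405 to 11243354 for stellate, 3965585 to 11141101 for endothelial and 2484617 to 6956406 for macrophage cells.

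The letters A, B and C are shared by the groups and the labels do not say what they mark. Deviations of same-letter libraries from their group means correlated over 0.1 for every letter between control and 2 weeks in endothelial cells (0.254, 0.181 and 0.149 for A, B and C) and in macrophages (0.346, 0.264 and 0.296), so there the data paired the libraries. In stellate cells the values were 0.101, 0.108 and 0.0344, and no comparison with the 4-week group was paired. A fit with the letter as a block was among the alternatives. The others were DESeq2, relative log expression factors, no filter on low counts, a fit of the 2 groups alone, each library left out, doublets kept, a stricter cell filter of 1000 genes and 5% mitochondrial UMIs, Leiden resolution 2 (41 clusters), equal cells per library, and only the clusters led by markers of the main subtype. Alternatives added after the data were seen were the stellate class with an unnamed cluster that stellate markers led, lists without library A of the 4-week group, a fit with the 2 sides of the widest gap in the level of Tsix as a covariate, shares of other classes at Leiden resolution 2, and overlaps under each setting. Cells of other classes entered no main comparison because they were few, and the unnamed cluster did not because the naming rule gave it no class.

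Tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.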

Results

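Non-parenchymal cells of mouse liver, sorted by FACS as a mixture of stellate cells, endothelial cells and macrophages, were profiled by droplet-based single-cell RNA-seq in 3 control libraries, 3 libraries after 2 weeks of carbon tetrachloride (CCl4) and 3 libraries after 4 weeks. CCl4 is a hepatotoxin used to bring about liver injury and fibrosis. Control libraries A, B and C held 11380767, 12737182 and 21400279 UMIs, the 2-week libraries 18249015, 35221781 and 26464924, and the 4-week libraries 28151076, 22035330 and 32343245. Median UMIs per barcode were 1766, 2751 and 2478 in controls, 3167, 4617.5 and 3456 at 2 weeks, and 3434, 2631 and 3959 at 4 weeks. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Levels are given as CPM of the summed UMIs of a class, mean ± SD over the 3 libraries of a group, and fold changes on the log2 scale ± SE, with n = 3 libraries per group throughout.

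Endothelial cells made up 56.7% of the cells kept from control libraries on average, 46.5% at 2 weeks and 32.1% at 4 weeks. Stellate cells made up 16.4%, 26.9% and 28.8%, and macrophages 24.0%, 19.7% and 19.4%. The sort sets these shares, and they are given as a description only. Within each class, different clusters held most cells of different groups. Stellate cells of controls lay to 97.6 to 99.2% in cluster 6 and those at 2 weeks in clusters 5 (32.7 to 53.5%) and 7 (34.9 to 42.6%). At 4 weeks cluster 3 held 51.1 and 65.0% of those of libraries B and C. In library A it held 73.4%, but only of the cells named stellate. Endothelial cells of controls lay in cluster 0 (73.5 to 81.6%) and those of the CCl4 libraries in cluster 1 (58.2 to 72.8%), except in 4-week library A, where 66.3% were in cluster 11. Macrophages of controls lay in cluster 2 (95.3 to 96.9%), those of the CCl4 libraries in cluster 4 (44.1 to 84.2%) and cluster 13 (25.3 to 28.3% at 2 weeks), except again in 4-week library A, with 96.5% in cluster 12. That library also held an unnamed cluster with stellate genes in the lead, 35.5% of its cells against at most 0.367% elsewhere, so that only 488 of its cells were named stellate. With that cluster added the number was 2742. The total of genes called in each comparison with the 4-week group is therefore also given without library A.

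**Figure D1:**
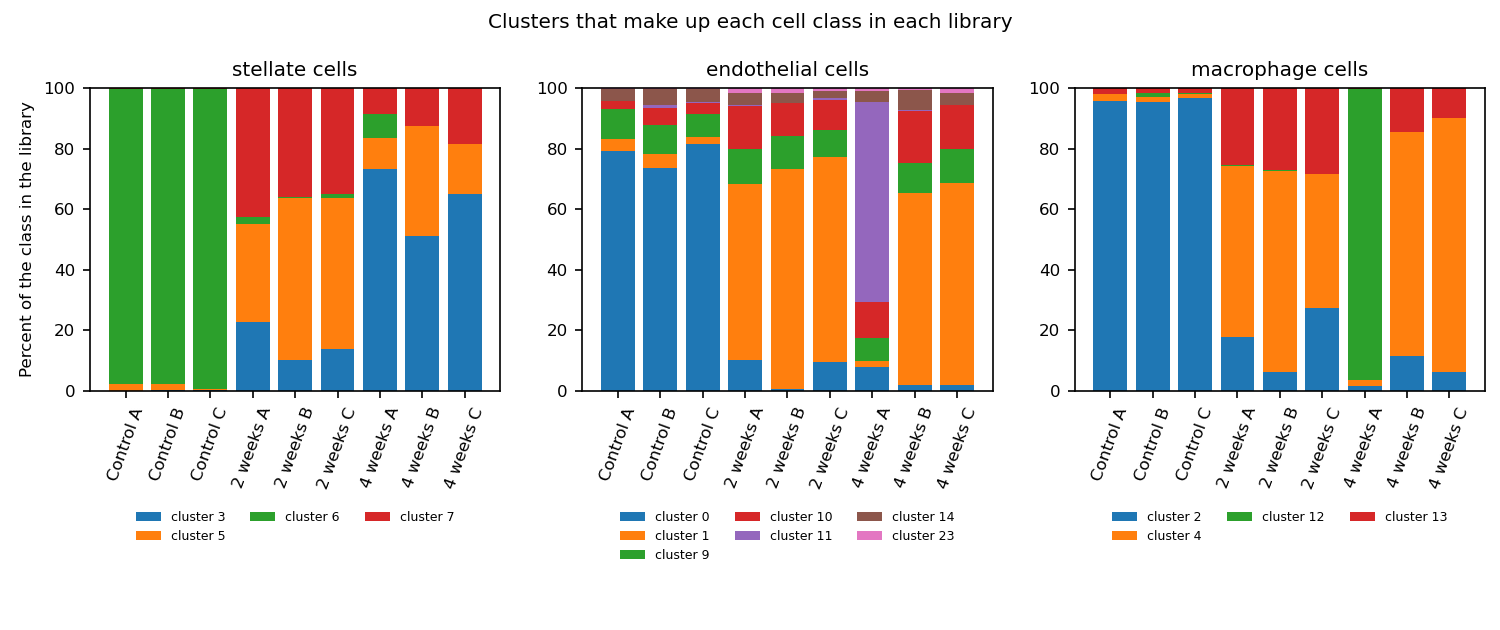
Stacked bars give the percent of stellate, endothelial and macrophage cells of each library (x axis) that lay in each cluster of the class. Controls and CCl4 libraries were held mostly by different clusters, and 96.5% of the macrophages of 4-week library A were in cluster 12.

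The first question was how stellate cells, which store vitamin A in the healthy liver and make collagen after injury, changed with CCl4. Transcripts of fibrillar collagen rose strongly. Col1a1 (ENSMUSG00000001506, GRCm38 chromosome 11, 94936224 to 94953042) went from 59.2 ± 8.61 CPM in controls to 1110 ± 98.6 at 2 weeks and 1908 ± 266 at 4 weeks (log2 fold changes 4.21 ± 0.16 and 4.99 ± 0.17, edgeR adjusted p = 5.19e-09 and 7.96e-10). Mmp2 (ENSMUSG00000031740, chromosome 8, 92827291 to 92853420), a gelatinase, rose from 93.8 ± 15.9 to 896 ± 210 and 771 ± 46.5 CPM (3.24 ± 0.18 and 3.03 ± 0.18, adjusted p = 9.75e-08 and 1.06e-07). Ecm1 (ENSMUSG00000028108, chromosome 3, 95734147 to 95739569), a secreted matrix protein abundant in control stellate cells, fell from 11242 ± 868 to 4567 ± 847 and 1620 ± 193 CPM (-1.30 ± 0.16 and -2.79 ± 0.17, adjusted p = 0.000101 and 1.38e-07). Fcna (ENSMUSG00000026938, chromosome 2, 25624666 to 25628030), which encodes the lectin ficolin A, fell from 3519 ± 607 to 505 ± 96.3 and 255 ± 24.6 CPM (-2.80 ± 0.17 and -3.79 ± 0.18, adjusted p = 2.99e-07 and 2.08e-08).

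Several genes were close to absent from control stellate cells. Fbn2 (ENSMUSG00000024598, chromosome 18, 58008623 to 58210487), a fibrillin, had no UMI in the controls and 23.0 ± 11.9 and 71.6 ± 16.6 CPM at 2 and 4 weeks, at least 59.4-fold and 189-fold higher against a floor of 3 UMIs over the control group. Ltbp2, a binding protein of elastic fibres, rose from 0.895 ± 0.351 to 64.3 ± 23.2 and 178 ± 73.4 CPM. Fhl2, a LIM-domain protein, rose from 5.62 ± 2.43 to 161 ± 4.99 and 202 ± 23.1 CPM. Plat, the tissue plasminogen activator, rose from 7.99 ± 1.57 to 220 ± 108 and 195 ± 18.7 CPM, and Tmem119 from 3.09 ± 1.77 to 68.3 ± 19.9 and 82.4 ± 2.99 CPM. Kcnj8 and Abcc9, neighbours on chromosome 6 (142564837 to 142571614 and 142587862 to 142702315), encode subunits of 1 ATP-sensitive potassium channel and fell together. Kcnj8 went from 673 ± 123 to 181 ± 56.5 and 106 ± 10.6 CPM and Abcc9 from 1385 ± 232 to 354 ± 37.7 and 280 ± 45.6 CPM. Hhip, an antagonist of hedgehog signals, fell from 215 ± 33.4 to 23.7 ± 8.50 and 10.7 ± 9.16 CPM, and Angptl6, a secreted angiopoietin-like protein, from 1893 ± 222 to 676 ± 255 and 215 ± 64.2 CPM. In a fit of clusters 5 and 6 alone, the clusters that the stellate marker list led rather than that of matrix-producing cells, Hhip (-2.02 and -2.76 at 2 and 4 weeks), Angptl6 (-0.40 at 2 weeks) and Ecm1 (-0.40 at 2 weeks) were no longer called. There nearly all control cells came from cluster 6 and most CCl4 cells from cluster 5, so the groups differ in cluster. With an unnamed stellate-led cluster added, Angptl6 was not called at 2 weeks (-1.48).

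Among the fixed lists, 12 of 17 collagen genes rose and none fell at 2 weeks (camera adjusted p = 9.63e-26), and 13 rose and 1 fell at 4 weeks (6.76e-27). Adjusted over the list alone 13 rose and 1 fell at both times, and with an estimated correlation the adjusted p = 0.0157 and 0.0156. Col1a2 rose from 301 ± 6.44 to 1610 ± 103 and 2599 ± 97.1 CPM, and Col3a1 from 381 ± 77.0 to 1900 ± 81.4 and 1742 ± 151 CPM. Of 18 crosslinking and remodelling genes, 12 rose and 1 fell at 2 weeks and 11 rose and 3 fell at 4 weeks, the same counts as adjusted over the list alone (adjusted p = 7.85e-11 and 2.22e-07; 0.00623 and 0.0156 with an estimated correlation). They included Lox, which crosslinks collagen (2.79 ± 0.33 and 3.35 ± 0.32), and the membrane protease Mmp14 (1.96 ± 0.17 and 1.98 ± 0.17). Of 19 matrix glycoproteins, 12 rose and 2 fell at 2 weeks and 10 rose and 4 fell at 4 weeks (13 and 3, and 10 and 5, adjusted over the list alone; adjusted p = 5.13e-06 and 0.0303, with 0.0281 and 0.165 with an estimated correlation). Among them, Sparc rose by 2.11 ± 0.15 and 1.46 ± 0.15.

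Of 16 contractile genes, 9 rose and 1 fell at 2 weeks and 8 rose and 1 fell at 4 weeks (11 and 1, and 10 and 1, adjusted over the list alone; camera adjusted p = 0.000127 and 0.000128, but adjusted p = 0.226 and 0.165 with an estimated correlation). Tpm1, a tropomyosin, rose from 83.6 ± 10.7 to 233 ± 17.6 and 274 ± 52.7 CPM. Acta2, the smooth muscle actin used as a marker of activated stellate cells, had 1.43 ± 0.702, 15.7 ± 10.2 and 29.1 ± 21.4 CPM. It missed the threshold at 2 weeks (3.39 ± 1.04, adjusted p = 0.0504) and passed it at 4 weeks (4.00 ± 1.02, adjusted p = 0.0275). The 4-week call of Acta2 ended without control A (3.83), B (4.25) or C (3.96), and in clusters 5 and 6 alone (4.54). Of 21 genes of quiescent stellate cells and retinoid storage, 1 rose and 11 fell at 2 weeks and 14 fell at 4 weeks, the same counts as adjusted over the list alone (adjusted p = 0.00109 and 3.46e-10; 0.336 and 0.124 with an estimated correlation). Reln fell from 2059 ± 164 to 1156 ± 199 and 694 ± 147 CPM and the growth factor gene Hgf from 318 ± 42.0 to 165 ± 21.2 and 127 ± 15.9 CPM. In clusters 5 and 6 alone, neither Reln (-0.18 and -0.40) nor Hgf (-0.20 and -0.31) was called. With the unnamed stellate-led cluster added, Reln was not called at 2 weeks (-0.82). Lrat, the enzyme that esterifies retinol, was not called (0.32 ± 0.30 and -0.38 ± 0.30, adjusted p = 0.447 and 0.385).

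Transcripts that mark other cells moved in the stellate class too. Of 7 portal fibroblast and smooth muscle genes, 6 rose at both times (7 and 6 adjusted over the list alone; camera adjusted p = 2.53e-09 and 4.18e-10; 0.0299 and 0.0233 with an estimated correlation). Dpt rose by 3.31 ± 0.26 and 3.83 ± 0.27, Eln, the elastin gene, by 1.73 ± 0.25 and 2.26 ± 0.25, and Mfap4 by 4.99 ± 0.38 and 5.10 ± 0.38. In clusters 5 and 6 alone, Dpt (0.30 and 1.03), Eln (0.26 and 0.53) and Mfap4 (0.06 and 1.10) were not called. Cluster 3, which held most cells named stellate at 4 weeks, had Mfap4 and Dpt among its leading genes. Whether portal fibroblasts within the class account for part of these rises was not tested. Of 4 cholangiocyte genes 2 rose at 2 weeks and 2 at 4 weeks (4 adjusted over the list alone at 4 weeks; adjusted p = 0.0859 and 0.0225, the latter 0.143 with an estimated correlation). Endothelial transcripts were lower after CCl4, 11 of 13 at 2 weeks and 12 at 4 weeks (11 and 13 adjusted over the list alone; adjusted p = 2.53e-09 and 3.46e-10; 0.156 and 0.143 with an estimated correlation). Macrophage transcripts were lower too, 4 and 3 of 13 (adjusted p = 0.000823 and 0.027; 0.452 and 0.693 with an estimated correlation). With the unnamed stellate-led cluster added, the latter was 0.0528. Immediate-early genes passed downward at 2 weeks, with 1 of 21 risen and 2 fallen (1 and 1 adjusted over the list alone; adjusted p = 0.0364; 0.728 with an estimated correlation), and did not pass at 4 weeks (0.309). Cdh5 fell from 52.7 ± 15.1 to 17.4 ± 2.14 and 16.6 ± 1.41 CPM and Timd4, a Kupffer cell gene, from 20.2 ± 4.66 to 3.61 ± 0.145 and 3.44 ± 1.95 CPM. With doublets kept, the calls of Cdh5 (-0.93 and -0.72) and of Dnase1l3 (-1.23 and -0.99) ended, while Dnase1l3 had fallen by 1.70 ± 0.23 and 1.96 ± 0.24 on the log2 scale without them.

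In all, 1733 of 11921 genes were higher and 1733 lower in stellate cells at 2 weeks, and 1732 were higher and 1613 lower at 4 weeks. Without 4-week library A the totals were 3722 and 3349 in place of 3466 and 3345. Without control C the 2-week total was 2048, and in clusters 5 and 6 alone the totals were 1768 and 885. With a split of the libraries by Tsix, described below, as a covariate the 2-week total was 1105.

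Between 4 and 2 weeks, which asks how stellate cells changed as exposure went on, 608 genes were higher and 655 lower at 4 weeks. Ecm1 fell further (-1.50 ± 0.16, edgeR adjusted p = 0.000367), as did Fcna (-0.99 ± 0.16, 0.00362), the succinate receptor Sucnr1 (-1.58 ± 0.17, 0.000367) and Spon2, a secreted spondin (-1.67 ± 0.21, 0.00194). Col1a1 and Col1a2 rose further (0.78 ± 0.14, adjusted p = 0.00521, and 0.69 ± 0.11, adjusted p = 0.00352), as did Ahnak2 (1.53 ± 0.20, 0.00191). Of 21 quiescent stellate genes 9 fell (1 rose and 13 fell adjusted over the list alone; camera adjusted p = 2.08e-07; 0.303 with an estimated correlation). Of 18 interferon response genes 8 fell (11 adjusted over the list alone; adjusted p = 2.08e-07; 0.579 with an estimated correlation). Of 17 collagens 4 rose, also adjusted over the list alone (adjusted p = 0.0354; 0.579 with an estimated correlation), and without 4-week library A the adjusted p = 0.0559. Of 19 matrix glycoproteins 2 rose and 7 fell (3 and 8 adjusted over the list alone; adjusted p = 0.015; 0.303 with an estimated correlation). Of 15 TGF-beta response genes 3 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.015; 0.303 with an estimated correlation). With the unnamed stellate-led cluster added, the calls of Ecm1 (-0.97), Fcna (-0.56), Col1a1 (0.47), Col1a2 (0.47), Ahnak2 (1.06) and Sucnr1 (-1.12) ended and 493 genes were called. The lists of collagens and matrix glycoproteins did not pass there (adjusted p = 0.351 for each), while against controls the interferon response passed upward at 2 weeks and downward at 4 weeks (0.0334 and 0.0428, in place of 0.0661 and 0.169). In clusters 5 and 6 alone 149 genes were called, and not Fcna (-0.24), Col1a1 (0.59), Col1a2 (0.27) or Ahnak2 (-0.19). The total of 1263 was 893 without 4-week library A, 690 without 4-week B, 835 without 4-week C, 365 without 2-week B and 542 without 2-week C. It was 0 with the split by Tsix as a covariate.

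**Figure D2:**
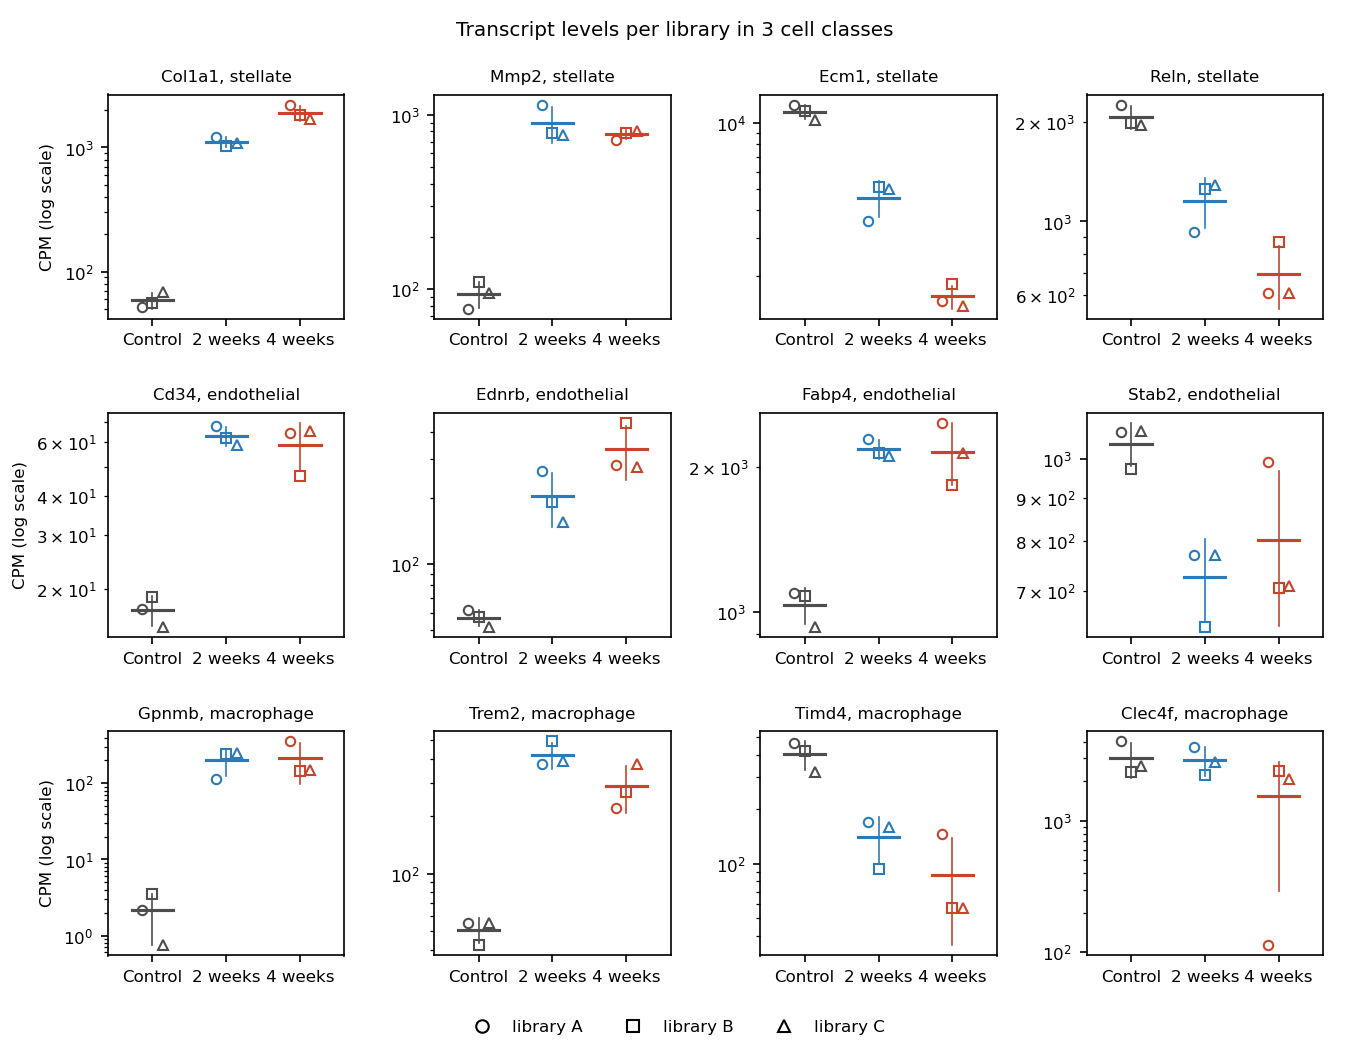
Points are the CPM (log scale) of single libraries for 4 genes in each of 3 cell classes, with marks by library letter, and lines are the mean ± SD of each group. Col1a1 and Mmp2 of every CCl4 library lay above the controls in stellate cells, and Clec4f was low in macrophages of 4-week library A alone.

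In endothelial cells, the question was how the sinusoidal lining, which is fenestrated and clears waste from blood in the healthy liver, changed with CCl4. Cd34 (ENSMUSG00000016494, GRCm38 chromosome 1, 194938819 to 194961279), a marker of capillaries elsewhere, rose from 17.0 ± 1.91 CPM to 62.9 ± 4.47 at 2 weeks and 58.8 ± 10.5 at 4 weeks (1.90 ± 0.14 and 1.81 ± 0.14, edgeR adjusted p = 9.59e-06 and 1.11e-05). Ednrb (ENSMUSG00000022122, chromosome 14, 103814625 to 103844402), an endothelin receptor, rose from 57.0 ± 4.92 to 204 ± 56.5 and 333 ± 91.4 CPM (1.84 ± 0.24 and 2.55 ± 0.24, adjusted p = 0.00281 and 0.000711). Fabp4 (chromosome 3, 10204088 to 10208576), a fatty acid carrier of capillary endothelium, rose from 1035 ± 89.0 to 2171 ± 97.2 and 2143 ± 314 CPM (1.07 ± 0.13 and 1.05 ± 0.13, adjusted p = 0.00058 and 0.000484). The imprinted gene Mest rose from 32.3 ± 2.04 to 143 ± 15.9 and 87.8 ± 14.3 CPM. Csrp2 rose from 153 ± 9.21 to 416 ± 37.2 and 381 ± 26.1 CPM, and the tetraspanin gene Cd63 from 72.5 ± 13.5 to 186 ± 18.3 and 229 ± 22.9 CPM. Ltbp4 fell from 593 ± 18.2 to 289 ± 34.5 and 286 ± 51.2 CPM (-1.04 ± 0.13 and -1.05 ± 0.13, adjusted p = 0.000749 and 0.000621). Gas6, a ligand of TAM receptors, fell from 316 ± 18.6 to 169 ± 5.67 and 163 ± 28.8 CPM, and the cytokine receptor gene Cntfr from 56.7 ± 4.73 to 24.5 ± 3.49 and 21.3 ± 1.57 CPM.

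Of 24 cell cycle genes, 16 rose and 1 fell at 2 weeks and 6 rose and 1 fell at 4 weeks (17 and 1, and 15 and 2, adjusted over the list alone; camera adjusted p = 1.02e-14 and 2.74e-06, but adjusted p = 0.168 and 0.243 with an estimated correlation). Cdk1, the mitotic kinase, rose from 6.82 ± 0.257 to 22.1 ± 1.23 CPM at 2 weeks and was also called at 4 weeks (1.69 ± 0.15 and 0.93 ± 0.16, edgeR adjusted p = 4.48e-05 and 0.00466). Ccnb2 rose by 2.50 ± 0.38 and 1.80 ± 0.41, and Ube2c by 2.54 ± 0.33 and 1.60 ± 0.35. The 4-week call of Ccnb2 ended without 4-week C (1.46), control A (1.62) or control C (1.46), and that of Ube2c without 4-week B (1.66), 4-week C (1.37), control A (1.32) or control B (1.63). In a fit of the control and 4-week libraries alone Ccnb2 was not called (1.77), nor was Ube2c with equal cells per library (1.20). Of 19 capillary and basement membrane genes, 2 rose and 2 fell at 2 weeks and 5 rose and 2 fell at 4 weeks (2 and 2, and 9 and 2, adjusted over the list alone; adjusted p = 0.0458 and 0.000199, or 0.508 and 0.243 with an estimated correlation). With the library letter as a block the first of these was 0.0518. Col4a1 and Col4a2, the chains of basement membrane collagen, were not called at 2 weeks (0.09 ± 0.13 and 0.13 ± 0.12) and rose at 4 weeks by 0.68 ± 0.13 and 0.82 ± 0.12, the call of Col4a1 ending without control C (0.65).

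Of 18 genes of sinusoidal identity, 1 rose and 5 fell at 2 weeks and 1 rose and 3 fell at 4 weeks (2 and 8 at each time adjusted over the list alone). The list passed at 4 weeks only (camera adjusted p = 0.057 and 0.0197; the latter 0.243 with an estimated correlation). Dnase1l3, a DNase, fell from 2429 ± 202 to 1360 ± 150 and 1408 ± 111 CPM, while Lyve1, the hyaluronan receptor, rose from 433 ± 125 to 751 ± 49.0 and 847 ± 58.0 CPM. The scavenger receptor Stab2 (chromosome 10, 86841198 to 87008025) had 1041 ± 60.0, 726 ± 79.0 and 802 ± 165 CPM and was called at 2 weeks alone (-0.52 ± 0.14, adjusted p = 0.0293; -0.38 ± 0.14, adjusted p = 0.15, at 4 weeks). That call ended without 2-week B (-0.43) or C (-0.57) or control A (-0.50), B (-0.57) or C (-0.50). Ehd3 fell by 0.51 ± 0.14 and 0.67 ± 0.14 on the log2 scale. The call ended at 2 weeks without 2-week A (-0.51), 2-week B (-0.43), control B (-0.54) or control C (-0.47) and at 4 weeks without 4-week C (-0.66) or control C (-0.63). Of 12 pericentral endothelial genes, 3 rose and 1 fell at 2 weeks and 4 rose and 1 fell at 4 weeks (3 and 2, and 6 and 1, adjusted over the list alone; adjusted p = 0.269 and 0.000199, the latter 0.259 with an estimated correlation). Wnt9b had 20.4 ± 3.88, 44.5 ± 3.49 and 71.7 ± 26.1 CPM and rose by 1.80 ± 0.26 at 4 weeks (adjusted p = 0.00524), and Pcdh17 rose by 1.27 ± 0.17. In sinusoidal clusters alone Wnt9b at 4 weeks (0.63), Stab2 at 2 weeks (-0.38) and Ehd3 (-0.43 and -0.54) were not called. Of 14 periportal endothelial genes 2 rose and 2 fell at 2 weeks and 2 rose and 1 fell at 4 weeks, and the list did not pass (adjusted p = 0.976 and 0.085). At 2 weeks its median and mean fold changes were above 0 while camera's direction was down.

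Of 17 interferon response genes, 6 rose and none fell in endothelial cells at 2 weeks (8 adjusted over the list alone; camera adjusted p = 2.82e-05; 0.508 with an estimated correlation). At 4 weeks none was called, and camera gave a lower list at adjusted p = 0.0422 (0.573 with an estimated correlation, and 0.355 without 4-week library A). Irf7, a transcription factor of the interferon response, had 61.5 ± 13.5, 124 ± 7.94 and 64.9 ± 11.4 CPM (1.02 ± 0.16 at 2 weeks, edgeR adjusted p = 0.00276). Rtp4 rose by 0.92 ± 0.20 at 2 weeks, a call that ended without 2-week B (0.88), 2-week C (0.90), control B (0.77) or control C (0.89). Xaf1 rose by 0.82 ± 0.17, a call that ended without 2-week B (0.77) or control C (0.72). Stellate transcripts were also higher in the endothelial class, 4 of 13 at 2 weeks and 5 at 4 weeks (adjusted p = 8.03e-05 and 2.27e-12; 0.508 and 0.243 with an estimated correlation). So were portal fibroblast and smooth muscle genes, 4 and 6 of 7 (5 and 6 adjusted over the list alone; adjusted p = 6.99e-05 and 9.9e-14; 0.328 and 0.0561 with an estimated correlation). Col1a1 there went from 1.09 ± 0.381 to 12.98 ± 0.143 and 27.0 ± 6.16 CPM. Col3a1 went from 6.80 ± 2.77 to 42.9 ± 4.57 and 49.8 ± 10.5 CPM, and Mfap4 from 0.361 ± 0.185 to 5.03 ± 0.854 and 7.69 ± 4.85 CPM, against far higher levels in stellate cells of the same libraries. Macrophage transcripts were lower at 2 weeks, 3 of 13 (adjusted p = 0.00687; 0.77 with an estimated correlation), and not called at 4 weeks (0.0941). Lists with no called member also passed at 4 weeks, hepatocyte transcripts upward and immediate-early genes downward (adjusted p = 0.0226 for each; 0.573 for each with an estimated correlation).

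Of 11962 endothelial genes, 957 were higher and 736 lower at 2 weeks and 375 were higher and 232 lower at 4 weeks. Without 4-week library A the totals were 2186 and 773 in place of 1693 and 607. The 2-week total was 1063 without 2-week A, 513 without 2-week B, 850 without control B, 561 without control C and 291 with the split by Tsix as a covariate. The 4-week total was 351 without 4-week B, 403 without 4-week C, 362 without control A, 253 without control C, 358 with the split by Tsix as a covariate and 360 in a fit of the control and 4-week libraries alone.

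Between 4 and 2 weeks, 483 endothelial genes were higher and 644 lower. Gpx3, a secreted glutathione peroxidase, rose from 39.4 ± 5.42 to 68.2 ± 4.81 CPM (0.79 ± 0.11, edgeR adjusted p = 0.00738). Of the interferon response genes 8 of 17 fell (13 adjusted over the list alone; camera adjusted p = 1.27e-12; 0.454 with an estimated correlation), and Irf7 fell by 0.93 ± 0.16 on the log2 scale (adjusted p = 0.0119). Without 2-week B, which ended that call, its fold change was -0.98. Of 24 cell cycle genes 1 fell, and the list passed (0.00041; 0.454 with an estimated correlation). Of 12 pericentral genes 2 rose (2 rose and 1 fell adjusted over the list alone; 0.0448; 0.653 with an estimated correlation), and of 15 TGF-beta response genes 4 rose, also adjusted over the list alone (0.00502; 0.454 with an estimated correlation). Stellate transcripts rose, 2 of 13 (3 adjusted over the list alone; 0.0298; 0.731 with an estimated correlation, and 0.106 without 4-week library A), as did 2 of 7 portal fibroblast genes (4 adjusted over the list alone; 0.00867; 0.454 with an estimated correlation). The total of 1127 was 609 without 4-week A, 107 without 4-week B, 252 without 2-week A, 34 without 2-week B and 539 without 2-week C, and 0 with the split by Tsix as a covariate.

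Macrophages were compared to see how Kupffer cells, the resident macrophages of the sinusoid, and other macrophages changed with CCl4. Gpnmb (ENSMUSG00000029816, GRCm38 chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, rose from 2.15 ± 1.40 CPM to 202 ± 76.7 at 2 weeks and 217 ± 119 at 4 weeks (6.58 ± 0.71 and 6.69 ± 0.71, edgeR adjusted p = 0.00274 and 0.00273). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), a lipid-sensing receptor, rose from 50.8 ± 7.53 to 419 ± 64.9 and 289 ± 79.8 CPM (3.04 ± 0.21 and 2.51 ± 0.21, adjusted p = 1.32e-05 and 2.26e-05). Cd63 rose from 43.2 ± 3.89 to 369 ± 107 and 353 ± 98.5 CPM, and the chemokine gene Ccl9 from 27.8 ± 9.52 to 135 ± 3.40 and 129 ± 33.0 CPM. C6 (ENSMUSG00000022181, chromosome 15, 4727175 to 4814967), a complement component, fell from 789 ± 43.4 to 227 ± 75.3 and 167 ± 24.7 CPM (-1.80 ± 0.22 and -2.24 ± 0.23, adjusted p = 0.000761 and 0.000121). Timd4 (chromosome 11, 46810800 to 46844332), a phosphatidylserine receptor of resident Kupffer cells, had 402 ± 71.4, 141 ± 41.6 and 86.8 ± 51.2 CPM (-1.51 ± 0.41 and -2.20 ± 0.42, adjusted p = 0.0375 and 0.0165). The 2-week call of Timd4 ended without 2-week A (-1.66), B (-1.28) or C (-1.60) or control A (-1.40), B (-1.47) or C (-1.64), and the 4-week call without control A (-2.09). In clusters led by Kupffer markers alone (-0.28) or with no filter on low counts (-1.48), Timd4 was not called at 2 weeks.

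Of 16 genes of lipid and scar-associated macrophages, 11 rose at 2 weeks and 10 at 4 weeks and none fell (13 and 12 rose adjusted over the list alone; camera adjusted p = 5.44e-19 and 1.14e-12; 0.0069 and 0.00742 with an estimated correlation). The integrin gene Itgax rose by 2.54 ± 0.30 and 2.60 ± 0.30, and the tetraspanin gene Cd9 by 1.68 ± 0.20 at 2 weeks, with a call at 4 weeks too. Spp1, osteopontin, had 1.84 ± 1.84, 15.7 ± 11.3 and 19.6 ± 5.36 CPM and was called at both times (adjusted p = 0.0433 and 0.0416). Its 2-week call ended when any 1 library other than 2-week A was left out (2.45 to 4.39) and its 4-week call when any 1 other than 2-week A or B was (2.85 to 4.69). Of 15 monocyte-derived macrophage genes 8 rose at both times and none fell (10 and 9 adjusted over the list alone; adjusted p = 2.43e-07 and 2.17e-11; 0.0262 and 0.00742 with an estimated correlation). S100a6 rose from 4.53 ± 2.44 to 20.7 ± 3.36 and 35.9 ± 5.56 CPM, Lgals1 by 2.35 ± 0.35 and 2.34 ± 0.35 on the log2 scale, and S100a4 by 3.17 ± 0.53 at 4 weeks. Ccr2, the monocyte chemokine receptor, had 5.20 ± 1.88, 61.1 ± 24.4 and 72.1 ± 53.6 CPM (adjusted p = 0.0302 and 0.0329). Its 2-week call ended without 2-week A (3.33), 2-week B (3.41), control A (3.54), control B (3.29) or control C (3.86), and its 4-week call without 2-week B (3.78), 4-week C (2.98), control A (3.78), control B (3.53) or control C (4.09). With the library letter as a block, Ccr2 was not called at 2 weeks (3.67), and it was not called at 4 weeks in a fit of the control and 4-week libraries alone (3.79). In clusters led by Kupffer markers alone, Spp1 (2.35 and 3.18), Itgax (1.65 and 1.92), S100a6 (0.29 and 1.41) and Lgals1 (1.52 and 1.43) were not called. With equal cells per library Spp1 was not called either (2.91 and 3.11).

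Of 18 genes of Kupffer cell identity, 1 rose and 4 fell at 2 weeks and 1 rose and 6 fell at 4 weeks (1 and 5, and 1 and 8, adjusted over the list alone; camera adjusted p = 0.0491 and 1.34e-06; 0.286 and 0.0247 with an estimated correlation). Clec4f (chromosome 6, 83644542 to 83656187), the lectin that marks Kupffer cells, had 3005 ± 889, 2900 ± 723 and 1540 ± 1246 CPM and was not called (-0.05 ± 0.93 and -0.97 ± 0.94, adjusted p = 0.974 and 0.546). Its level in 4-week libraries A, B and C was 113, 2409 and 2098 CPM. Xlr fell from 50.5 ± 14.2 to 28.3 ± 1.44 and 14.9 ± 1.15 CPM and the complement gene C2 from 101 ± 5.82 to 37.5 ± 4.65 and 29.6 ± 11.4 CPM. In clusters led by Kupffer markers alone, Xlr (0.30 and -0.07) and C2 (-0.34 and -0.63) were not called. Of 18 phagocytosis and complement genes, 5 rose and 1 fell at 2 weeks and 1 rose and 2 fell at 4 weeks (6 and 2 adjusted over the list alone at 2 weeks), and the list did not pass (adjusted p = 0.254 and 0.799). C1qb rose from 2900 ± 1150 to 6472 ± 752 CPM at 2 weeks, but was not called in clusters led by Kupffer markers alone (0.90).

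Of 18 interferon response genes, 12 rose and none fell in macrophages at 2 weeks (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.42e-07; 0.452 with an estimated correlation). At 4 weeks 1 fell and the list did not pass (0.983, with camera's direction down and the median and mean above 0). Ifit1 went from 21.6 ± 4.63 to 47.2 ± 2.36 and 22.9 ± 7.69 CPM and Usp18 from 18.7 ± 3.41 to 38.0 ± 0.617 and 22.2 ± 7.36 CPM. Of 18 inflammatory genes, 1 rose and 6 fell at 2 weeks and 4 fell at 4 weeks (1 and 7, and none and 4, adjusted over the list alone; adjusted p = 0.108 and 0.00614, the latter 0.683 with an estimated correlation). The cytokine gene Il6 fell from 21.9 ± 6.95 to 5.18 ± 0.364 and 2.84 ± 2.23 CPM (-2.08 ± 0.37 and -3.20 ± 0.42, adjusted p = 0.00447 and 0.00104). Cxcl9 fell by 1.03 ± 0.20 and 0.92 ± 0.20 on the log2 scale, the 4-week call ending without 4-week C (-0.88). Il10 fell by 1.14 ± 0.25 and 1.42 ± 0.26 on the log2 scale, the 2-week call ending without 2-week B (-1.06) or control B (-0.89). In clusters led by Kupffer markers alone, Ifit1 at 2 weeks (0.84) and Il6 (-1.70) and Il10 (-1.65) at 4 weeks were not called. With a stricter cell filter Il10 was not called (-0.89 and -1.21). At 2 weeks, lists of cell cycle genes and hepatocyte transcripts, with no called member, did not pass (0.0638 and 0.0685) but did with the library letter as a block (0.0401 and 0.0388). Immediate-early genes, which respond to handling, passed downward at 4 weeks with 1 of 21 fallen (0.0161; 0.77 with an estimated correlation).

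Endothelial transcripts were lower in the macrophage class, 9 of 13 at 2 weeks and 10 at 4 weeks (11 and 12 adjusted over the list alone; camera adjusted p = 5.36e-09 and 9.57e-14; 0.286 and 0.0977 with an estimated correlation). Cdh5 there fell from 642 ± 94.7 to 315 ± 74.6 and 256 ± 41.2 CPM, and at 2 weeks was not called in clusters led by Kupffer markers alone (-0.48). Stellate transcripts were higher, 3 and 4 of 13 (5 adjusted over the list alone at 4 weeks; adjusted p = 0.0114 and 2.94e-08; 0.722 and 0.301 with an estimated correlation). Also higher were 2 and 3 of 4 portal fibroblast genes (0.0116 and 2.48e-05; 0.286 and 0.0478 with an estimated correlation). Col1a1 in macrophages went from 1.27 ± 0.208 to 11.9 ± 2.97 and 27.3 ± 6.82 CPM, close to its levels in endothelial cells. Of 11115 macrophage genes, 1092 were higher and 1110 lower at 2 weeks and 715 were higher and 705 lower at 4 weeks. Without 4-week library A the totals were 2890 and 1496 in place of 2202 and 1420. The 2-week total was 1023 without 2-week A, 638 without 2-week B, 1160 without control B, 759 without control C and 157 with the split by Tsix as a covariate. The 4-week total was 534 without 4-week C, 900 without control A, 834 without control B, 513 without control C and 932 with that covariate. In clusters led by Kupffer markers alone the totals were 732 and 238. There 4-week library A had 22 cells, under the minimum of 50, and was left out, so all values of these clusters rest on the other 8 libraries. The total was 893 at 4 weeks in a fit of the control and 4-week libraries alone.

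Between 4 and 2 weeks, edgeR called 0 macrophage genes, with 1289 at an unadjusted p under 0.05 and 82 called by DESeq2. Without 4-week library A edgeR called 27, without 4-week C 17, without 2-week B 1 and without control A 31. Lists passed nonetheless, with no member called over all genes. The interferon response list was lower at 4 weeks (12 of 18 fell adjusted over the list alone; camera adjusted p = 6.76e-20; 0.165 with an estimated correlation), as were lipid and scar-associated genes (4 fell adjusted over the list alone; 0.000258; 0.143 with an estimated correlation). Lower too were Kupffer identity (1 fell adjusted over the list alone; 0.000258; 0.143 with an estimated correlation) and 11 genes of MHC class II presentation (0.0333; 0.695 with an estimated correlation, and 0.0789 without 4-week library A). Stellate transcripts (4 rose adjusted over the list alone; 4.7e-05; 0.433 with an estimated correlation) and portal fibroblast genes (0.0457; 0.365 with an estimated correlation) were higher.

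Tsix, annotated on the X chromosome (103431517 to 103484957) antisense to Xist, split the libraries across the groups. Its level was 7.60 to 16.4 CPM in control A and all 2-week libraries and 39.7 to 114 CPM in controls B and C and all 4-week libraries, in each of the 3 classes. Tsix and Xist reads may be mixed unless counting used strand, which is not given, so the level is uncertain. Xist (618, 669 and 654 CPM in stellate controls A, B and C) argues against a fixed share of its reads. Tsix was called between 4 and 2 weeks (2.91 in stellate cells), so its parting of these groups is no separate evidence. Only controls lay on both sides, so a fit with the side as covariate estimated it from control A against B and C. There edgeR called 1105, 2823 and 0 stellate genes at 2 weeks, 4 weeks and between 4 and 2 weeks, 291, 358 and 0 endothelial genes and 157, 932 and 0 macrophage genes, where macrophages had 0 of the last kind without the covariate too. An unadjusted p under 0.05 between 4 and 2 weeks was found for 1395 stellate, 1099 endothelial and 417 macrophage genes. Of the 1263 stellate and 1127 endothelial genes called without it, 96.1% and 98.6% kept their direction. Their median log2 fold change in that direction went from 0.61 to 0.53 and from 0.51 to 0.37, while the median SE rose from 0.139 to 0.278 and from 0.120 to 0.206, so in the median wider errors weighed more in ending the calls than smaller folds. Without control A, on the side of controls B and C, the 4-week totals were 2901 stellate, 362 endothelial and 900 macrophage genes. The other side had 1 control, too few to test. The interferon gene Rtp4 was higher at 2 weeks than at 4 weeks in stellate cells (340 ± 77.3 and 175 ± 35.3 CPM) and endothelial cells (247 ± 16.7 and 114 ± 31.5 CPM), by -0.95 ± 0.20 and -1.11 ± 0.20 from 2 to 4 weeks (edgeR adjusted p = 0.0162 and 0.0166). The stellate call of Rtp4 ended without 2-week B (-0.84), 2-week C (-0.83) or 4-week B (-0.92). The endothelial call ended without 2-week A (-1.16), 2-week B (-1.07) or 4-week B (-1.03).

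With that covariate, log2 fold changes between 4 and 2 weeks were -1.34 ± 0.29 for Ecm1, -0.58 ± 0.27 for Fcna, 0.52 ± 0.28 for Col1a1, 0.72 ± 0.20 for Col1a2 and -0.49 ± 0.34 for Rtp4 in stellate cells. In endothelial cells they were 0.81 ± 0.23 for Gpx3, -0.43 ± 0.22 for Irf7 and -0.61 ± 0.31 for Rtp4. Lists in this fit were tested at the preset correlation only. The interferon response list still passed there between 4 and 2 weeks in endothelial cells (camera adjusted p = 0.0226) and macrophages (0.00223), but not in stellate cells (0.203). With an estimated correlation it had passed in none of the 3 classes between 4 and 2 weeks even without the covariate. At 2 weeks against controls it passed in macrophages (0.00242) and not in endothelial cells (0.13), nor did it at 4 weeks there (0.559). In stellate cells the lists of matrix glycoproteins (0.163) and the TGF-beta response (0.241) no longer passed between 4 and 2 weeks, nor immediate-early genes at 2 weeks (0.865) and macrophage transcripts at 4 weeks (0.0702). In the endothelial class, pericentral genes (0.639), portal fibroblast genes (0.194) and the TGF-beta response (0.579) no longer passed between 4 and 2 weeks, nor the capillary list at 2 weeks (0.295). In the macrophage class, lipid and scar-associated genes (0.21) and portal fibroblast genes (0.938) no longer passed between 4 and 2 weeks. The lists of stellate transcripts in endothelial cells and macrophages and of MHC class II presentation in macrophages changed direction between 4 and 2 weeks. In stellate cells the 2-week calls of Fbn2, without a control UMI, of Ltbp2 (6.47) and of Angptl6 (-1.37) and the 4-week call of Acta2 (3.84) ended. In the endothelial class those at 2 weeks of Ednrb (1.73), Lyve1 (0.98), Stab2 (-0.57), Ehd3 (-0.50), Irf7 (0.70), Rtp4 (0.60), Xaf1 (0.45) and Mfap4 (4.77) did, and at 4 weeks that of Ccnb2 (1.61). In the macrophage class those at 2 weeks of Gpnmb (6.55), Lgals1 (2.37), Ifit1 (0.92), Usp18 (0.93), Il6 (-1.41), Il10 (-0.87) and C1qb (0.62) ended. Calls of Ccr2 (3.51 and 3.78), Spp1 (3.46 and 3.34) and Timd4 (-1.72 and -2.09) in the macrophage class ended at both times.

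**Figure D3:**
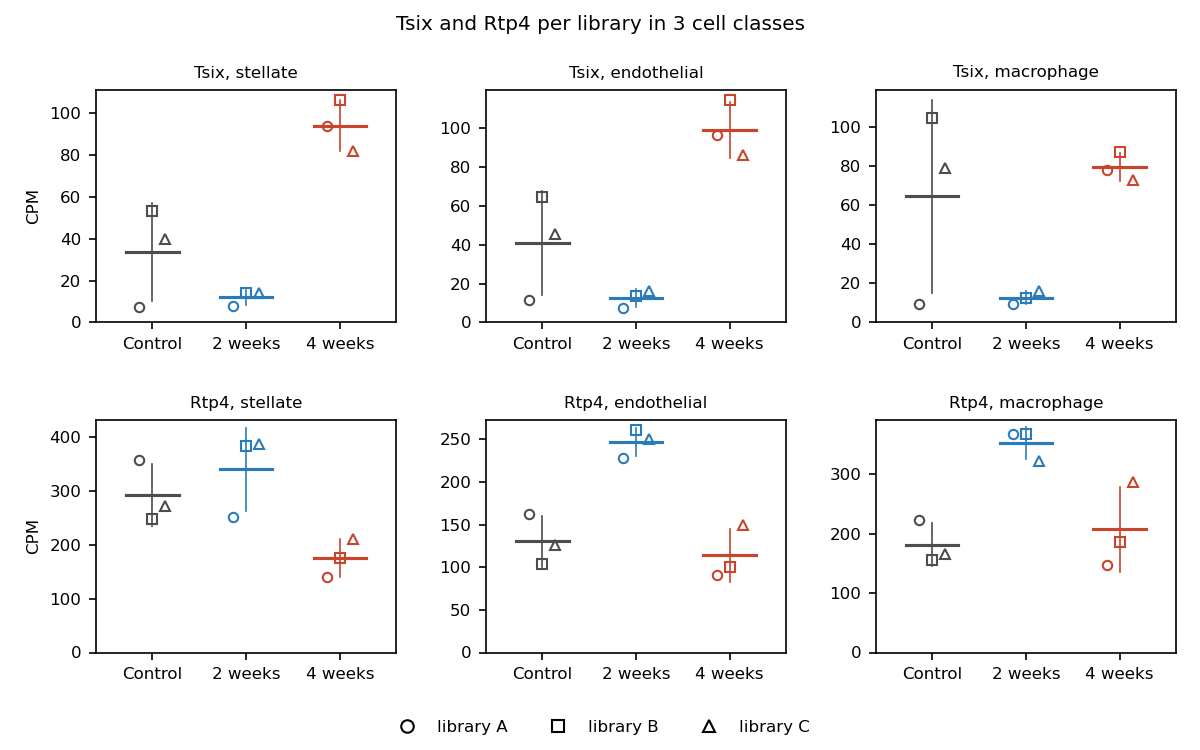
Points are the CPM of Tsix and Rtp4 in single libraries of 3 cell classes, with marks by library letter, and lines are the mean ± SD of each group. Tsix of control A lay with the 2-week libraries (7.60 to 16.4 CPM) and that of controls B and C lay at 39.7 CPM or above.

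The 2-week and 4-week comparisons shared their controls, and their calls overlapped. In stellate cells 1056 genes were higher and 1044 lower in both, against 251.8 and 234.5 from independent lists of those sizes and at most 1 in simulations of unchanged groups, and 8 moved in opposite directions. In endothelial cells 234 were higher and 112 lower in both (30.0 and 14.3 from independent lists, 0 in simulations), and in macrophages 498 and 498 (70.2 and 70.4, with a simulated mean of 0.1), with none opposite in either class. The correlation of fold changes over genes, which are not independent replicates, was 0.878, 0.591 and 0.832 in stellate, endothelial and macrophage cells against 0.542, 0.497 and 0.515 in simulations, and the covariance was 0.433, 0.0716 and 0.217 against 0.0190, 0.0150 and 0.0279. Part of the excess of shared calls may come from the shared controls. The simulations held no changed gene, so they cannot show how many shared calls the same controls would give where many genes change. Of 2100, 346 and 996 genes shared in the same direction, 1306, 124 and 312 were shared without control C, 2188, 459 and 1128 without 4-week library A and 704, 84 and 114 with the side of Tsix as a covariate. In endothelial cells the number was also 183 without 2-week B, 216 without 4-week C and 211 without control B, and in macrophages 591 without 2-week A, 401 without 2-week B, 390 without 4-week C and 538 without control B.

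At 1000 UMIs per cell, the share of stellate cells with a UMI of Col1a1 was 5.08 ± 0.649% in controls, 52.1 ± 4.28% at 2 weeks and 69.9 ± 2.43% at 4 weeks, against at most 3.64% in endothelial cells or macrophages of any library. Without thinning the shares were 13.3, 82.5 and 91.0%, against at most 9.30%. The share with a UMI of Reln was 85.2 ± 2.29, 63.8 ± 4.40 and 41.9 ± 6.12% (98.1, 91.4 and 70.7% without thinning), against at most 9.67% in other classes. Among endothelial cells 28.0 ± 6.09, 43.2 ± 1.74 and 45.5 ± 1.93% had a UMI of Lyve1 (43.1, 67.8 and 64.7% without thinning), against at most 2.01% in other classes. Among macrophages 33.7 ± 3.94, 12.6 ± 3.37 and 7.75 ± 3.52% had a UMI of Timd4 (56.5, 29.4 and 17.6% without thinning), against at most 2.79%. Trem2 had shares of 4.63 ± 0.806, 26.5 ± 4.36 and 20.9 ± 5.40% (9.87, 58.7 and 45.6% without thinning), against at most 2.09%. Each CCl4 group differed from controls without overlap in these 5 genes, at the smallest p that an exact two-sided permutation test of 3 against 3 libraries can give, 0.1, and chance gives no overlap for 10% of such comparisons. They were picked after their values were seen from 18 genes tested, of which 14 at 2 weeks and 16 at 4 weeks did not overlap with controls and 3 did not between 4 and 2 weeks. Shares that overlapped with controls were those of Lrat (exact permutation p = 0.3 and 0.3) and Wnt2 (0.5 and 0.2), and at 2 weeks those of Clec4g (0.8) and Vwf (0.6). Cells under 1000 UMIs were left out, 27, 4 and 13 stellate, 215, 19 and 73 endothelial and 122, 36 and 111 macrophage cells of controls A, B and C and 0 of the CCl4 libraries. Median UMIs per cell before thinning were 2215 to 5468 in stellate cells, 1725 to 3456 in endothelial cells and 1944 to 5520.5 in macrophages of single libraries.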

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

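The tests of a batch that parts the control libraries, of a handling response and of doublets among macrophages, and the side of Tsix as a covariate, were chosen only after the result was seen. Genes and lists are given here because they differed by a direct test, the comparison of the 4-week with the 2-week libraries. That test cannot tell the length of CCl4 exposure from a batch between these libraries.

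In stellate cells 1263 genes differed in that test and in endothelial cells 1127. Without 2-week B these totals were 365 and 34, the lowest with 1 library left out, and the report gives the others. With the side of the libraries in the level of Tsix as a covariate, edgeR called 0 in both, with 1395 and 1099 at an unadjusted p under 0.05. There the median size of the fold changes went from 0.61 to 0.53 in stellate cells and from 0.51 to 0.37 in endothelial cells and the median SE from 0.139 to 0.278 and from 0.120 to 0.206. In stellate cells the log2 fold changes of Ecm1 (-1.50), Fcna (-0.99), Spon2 (-1.67), Sucnr1 (-1.58), Col1a1 (0.78), Col1a2 (0.69) and Ahnak2 (1.53) were called whichever library was left out, as was Gpx3 (0.79) in endothelial cells. With the unnamed stellate-led cluster added, the calls of Ecm1, Fcna, Sucnr1, Col1a1, Col1a2 and Ahnak2 ended. The remaining stellate calls each ended without certain libraries. Fxyd6 (1.94) ended without any 1 CCl4 library other than 2-week A (1.68 to 2.12), and Ltbp2 (1.46) without any 1 library other than 2-week A or 4-week B (1.14 to 1.52). Sparc (-0.65) and Reln (-0.74) ended without 2-week B (-0.50 and -0.66), 2-week C (-0.63 and -0.64), 4-week A (-0.61 and -0.64) or 4-week C (-0.62 and -0.63). Angptl6 (-1.65) ended without 2-week B (-1.48), 2-week C (-1.47) or 4-week A (-1.65), and Mest (-1.54) without 2-week B (-1.37), 2-week C (-1.53) or 4-week C (-1.38). Rtp4 (-0.95) ended without 2-week B (-0.84), 2-week C (-0.83) or 4-week B (-0.92), and Tsix (2.91) without 2-week B (3.05) or 2-week C (3.04). Gpnmb (1.95) ended without any 1 library other than 2-week A, 4-week B or control B (1.68 to 1.94).

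Endothelial Mest (-0.70), Col4a2 (0.69), Irf7 (-0.93) and Col1a1 (1.05) ended without 2-week B (-0.61, 0.66, -0.98 and 1.05). Cdk1 (-0.76) and Xaf1 (-1.02) ended without 2-week B (-0.71 and -0.97) or 4-week B (-0.66 and -0.99). Col4a1 (0.59) and endothelial Rtp4 (-1.11) ended without 2-week A (0.59 and -1.16), 2-week B (0.56 and -1.07) or 4-week B (0.57 and -1.03). Endothelial Tsix (2.94) ended without any 1 library other than control A or B (2.71 to 3.20).

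The lists that passed between 4 and 2 weeks had these median log2 fold changes. In stellate cells the medians were 0.29 for collagens, -0.65 for the interferon response, -0.29 for matrix glycoproteins, -0.59 for quiescent stellate genes and 0.39 for the TGF-beta response. In endothelial cells they were -0.53 for the cell cycle, -0.84 for the interferon response, 0.29 for pericentral genes, 0.99 for portal fibroblast genes, 0.36 for stellate transcripts and 0.49 for the TGF-beta response. In macrophages they were -0.78 for the interferon response, -0.24 for Kupffer identity, -0.31 for lipid and scar-associated genes, -0.26 for MHC class II presentation, 0.71 for portal fibroblast genes and 0.42 for stellate transcripts. With an estimated correlation 0 of these lists passed. Without 4-week library A, stellate collagens, endothelial stellate transcripts and macrophage MHC class II presentation did not pass. With the side of Tsix as a covariate 8 did not pass and 3 changed direction, as named in the report.

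Of the cells outside the compared classes, neutrophils and plasmacytoid dendritic cells lay above every control library in each CCl4 library, while others such as B cells and hepatocytes did not. Neutrophils reached 1.49% of the cells in 2-week library A against at most 0.379% in a control library. At Leiden resolution 2, where part of that cluster was named dendritic, the share was 0.605% against at most 0.326%. Plasmacytoid dendritic cells reached 0.268% in 4-week library B, 17 cells, against at most 0.0522%. In 4-week library A they were 4 cells (0.0631%, 95% interval 0.0172 to 0.161%). Control C also had 4 (0.0522%, 0.0142 to 0.134%), so these 2 libraries cannot be told apart. An unnamed cluster with stellate markers in the lead held 35.5% of the cells of 4-week library A against at most 0.152% in a control library.

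The first pattern weighed was that genes that differed between 4 and 2 weeks moved alike in the 3 classes, with correlations over 2925 genes of 0.724 between stellate and endothelial cells, 0.659 between stellate cells and macrophages and 0.753 between endothelial cells and macrophages, and 357 of 359 genes called in both stellate and endothelial cells had 1 direction. Free RNA from other cells was argued against, since 58 genes higher at 4 weeks in both classes exceeded the log2 fold of the other class by a median of 0.102 (quartiles 0.0455 and 0.310) where the lower-level class would need 1.10. A difference between library batches may contribute, since the same difference correlated with that of controls B and C from control A, mice without CCl4, at 0.227, 0.374 and 0.427 in stellate, endothelial and macrophage cells (0.188, 0.304 and 0.273 without 4-week library A). Over the 357 genes controls B and C lay from control A in that direction by a median log2 of 0.0808 in stellate cells and 0.199 in endothelial cells, with 67.2% and 83.8% of the genes alike. The loss of all calls with the side of Tsix as covariate, which rests on the same controls and mainly widened errors, decides little too. A batch, which no label names, and a response to longer exposure both stay open.

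The next pattern was that 4-week library A stood apart from libraries B and C of its group in all 3 classes, with 67, 64 and 114 genes over 2-fold from both in stellate, endothelial and macrophage cells after erythroid genes were set aside. Stellate counts and list ratios in this paragraph took in the unnamed stellate-led cluster. A library without CCl4 was argued against in endothelial cells and macrophages. On genes shared by both CCl4 comparisons, its median position from controls (0) to the other 4-week libraries (1) was 0.726 and 0.928 there. In stellate cells the position was 0.996, but only for the 488 cells named stellate, of 2742 with the unnamed cluster. Of those 488, 73.4% lay in cluster 3 with most stellate cells of the other 4-week libraries, so the naming favoured that value. Free RNA from lysed red cells was argued against as the whole cause, since the number of other genes apart was at least 8.38 times that of either other 4-week library, although erythroid transcripts were higher by log2 ratios of 7.28, 5.19 and 7.09. Hepatocyte transcripts had median log2 ratios of -1.96, -2.24 and -2.68, with 0 of 19 higher than in both other libraries, and interferon genes -0.29, -0.38 and -0.77. A stress response during handling may contribute and cannot be told apart from a difference between animals, since the immediate-early list was higher by medians of 0.926, 0.839 and 0.609, under the 1 log2 unit set as the mark and above the 0.5 that would have argued against it.

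The last pattern was that stellate matrix transcripts were higher in endothelial cells and macrophages after CCl4. Free RNA from stellate cells may account for it in both classes, since Col3a1 as a share of its stellate level lay over 2-fold above the median share of the other stellate transcripts in 0 of 6 CCl4 libraries in endothelial cells and in 0 of 6 in macrophages. Droplets with both cells that the caller missed cannot be told apart from free RNA in either class. In endothelial cells keeping called doublets added at most 0.548% of cells and moved Col3a1 by -0.0175, which tests nothing, and in macrophages it moved Col3a1 by 1.01, from 2.27 to 3.27. The biological alternative, matrix genes expressed in endothelial cells or macrophages after CCl4, was not tested beyond these shares.

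Other splits of the same libraries were tested too. For a difference between any of the 3 groups, 1 of 100 splits drawn from 280, the real one, gave as many genes in each class. This argues against chance as the source of a difference between any groups. Stellate cells had 4438 genes against at most 2225, endothelial cells 2137 against 219 and macrophages 1897 against 1625 in other splits. The 2225 and 1625 came from splits that kept the 3 controls together and mixed the CCl4 libraries, which points to a structure of the samples in which the controls stand apart. Not all splits that keep the controls together were drawn. The drawn splits therefore do not decide whether 2 and 4 weeks differ beyond chance. With 2 groups there are 10 splits, too few for a share under 0.05. The real split gave 3397, 3067 and 876 genes in stellate cells for 2 weeks, 4 weeks and 4 against 2 weeks, with at most 0, 0 and 2 in others. In endothelial cells these were 2112, 360 and 912 against 0, 2 and 5. In macrophages they were 2904, 893 and 1 against 0, 0 and 31, and 2 of the 10 splits gave as many as the last.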

How the results depend on the processing

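The stellate class with the unnamed stellate-led cluster, lists without 4-week library A, the side of Tsix as a covariate, shares of other classes at Leiden resolution 2 and overlaps under each setting were alternatives chosen only after the result was seen. The genes behind these counts are the selection of the text, so their stability is that of a selection. Under settings other than leaving out a library, the number of genes called stayed within 1.5 times for 110 of 137 values, the overlap for 30 of 35 and the number of lists for 20 of 30. With a library left out it did for 70 of 108, 17 of 27 and 6 of 9. Of 442, 455 and 208 values of called stellate genes at 2 weeks, 4 weeks and 4 against 2 weeks under other settings, 416, 438 and 154 kept their direction and call. The numbers were 260 of 273, 245 of 251 and 99 of 110 in endothelial cells, and 272 of 305 and 233 of 251 in macrophages at 2 and 4 weeks. With 1 library left out, none changed direction. On simulated 2-week stellate counts with 200 genes changed, 69.6% of 2-fold changes were recovered, and depth was not varied.

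In clusters of the main subtype alone, which hold fewer cells, stellate cells had 1768, 885 and 149 genes called for 2 weeks, 4 weeks and 4 against 2 weeks, 1711 for any group and 616 shared by 2 and 4 weeks. Macrophages had 732, 238 and 3, with 568 for any group and 129 shared, all without 4-week library A, which had 22 cells there, under the minimum of 50. There the direction turned for Fxyd6 (-1.13) and Sucnr1 (0.19) in stellate cells at 2 weeks, Rtp4 in stellate cells at 4 weeks (0.0869), Ahnak2 in stellate cells between 4 and 2 weeks (-0.19) and Xlr in macrophages at 2 weeks (0.30), and the cause was not tested. Between 4 and 2 weeks stellate cells had 793 genes with equal cells per library and 493 with the unnamed cluster. A fit of 2 groups alone, with fewer libraries, gave 360 endothelial and 893 macrophage genes at 4 weeks. In macrophages between 4 and 2 weeks, where edgeR called 0, DESeq2 called 82, no filter on low counts gave 73, equal cells 23, doublets kept 17, the stricter cell filter 4 and the fit of 2 groups alone 1. The cause was not tested.

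The number of lists that passed in stellate cells was 9, 9 and 5 and with an estimated correlation 4, 3 and 0, with 3 between 4 and 2 weeks when the unnamed cluster was added. The report names the 3 stellate lists that this ended and the 2 it added. In endothelial cells 6, 9 and 6 became 0, 0 and 0, and in macrophages 7, 8 and 6 became 2, 4 and 0. Of 65 lists that passed, 13 did with an estimated correlation. Without 4-week library A, 61 passed, the report giving the other 4, and 28 others did, with 10 endothelial lists at 2 weeks and 13 and 14 macrophage lists at 4 weeks and between 4 and 2 weeks.

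With the side of Tsix as a covariate, which only the controls cross, stellate cells had 1105, 2823 and 0 genes for 2 weeks, 4 weeks and 4 against 2 weeks, 3179 for any group and 704 shared by 2 and 4 weeks. Endothelial cells had 291, 358 and 0, with 675 for any group and 84 shared, and macrophages 157, 932 and 0, with 1293 and 114. Macrophages had 0 between 4 and 2 weeks without the covariate too. Of 65 lists that passed, 49 did so in the same direction, and 19 others passed. The report gives the 13 that did not pass. Between 4 and 2 weeks the list of stellate transcripts turned from higher to lower in endothelial (adjusted p = 0.00271) and macrophage cells (8.00e-05), and that of MHC class II presentation from lower to higher in macrophages (0.000157).

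With a library left out, stellate cells had 2048 to 3722 genes at 2 weeks, 2399 to 3648 at 4 weeks, 365 to 1506 between them and 3068 to 4523 for any group, and shared 1306 to 2188. The endothelial class had 513 to 2186, 253 to 773, 34 to 1408 and 713 to 2395, and shared 124 to 459. The macrophage class had 638 to 2890, 513 to 1612, 0 to 31 and 529 to 2456, and shared 312 to 1128.

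With the library letter as a block, stellate cells had 3578, 3473 and 1544 genes and 4617 for any group, endothelial cells 1553, 629 and 982 and 1977, and macrophages 1848, 1153 and 5 and 1509. In stellate cells between control and 2 weeks (0.101, 0.108 and 0.0344) and in comparisons with the 4-week group, not every same-letter correlation was over 0.1, and not every library correlated best with its own letter. There the block ended the 4-week calls of Acta2 (3.86), Ccr2 (3.69) and Ccnb2 (1.83). It also passed lists at 4 weeks of periportal endothelial genes (adjusted p = 0.0245), of hepatocyte transcripts in macrophages (0.0377) and of the TGF-beta response in stellate cells (0.0245). Cholangiocyte genes in stellate cells passed at 2 weeks (0.0162) and between 4 and 2 weeks (0.0111). Apart from these and the blocked values in the report, the block changed no other call of a list or named gene.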

Other observations

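Gpnmb in stellate cells and the macrophage genes of 4-week library A were chosen only after their values were seen. Cells outside the 3 sorted classes were few, and their shares are set by the sort. Shares at Leiden resolution 2 were added after the shares were seen. Dendritic cells made up 0.412 ± 0.111% of the cells in controls, 1.06 ± 0.685% at 2 weeks and 1.06 ± 0.778% at 4 weeks (SD, n = 3 libraries). Of these, 276 cells before doublet removal formed cluster 21, led by cell cycle genes, and 258 of them were named macrophage at resolution 2, where the class made up 0.0880 ± 0.0864, 0.850 ± 0.846 and 1.08 ± 0.582%. B cells made up 0.219 ± 0.101, 0.515 ± 0.2995 and 0.510 ± 0.585%, and in 4-week libraries A, B and C alone 1.17, 0.0474 and 0.315%. T cells made up 0.174 ± 0.0269, 0.334 ± 0.222 and 0.319 ± 0.127%, and plasma cells 0.821 ± 0.191, 1.23 ± 0.0658 and 1.17 ± 0.555%. Neutrophils made up 0.289 ± 0.120% in controls, 0.900 ± 0.516% at 2 weeks and 1.10 ± 0.101% at 4 weeks. At resolution 2 the same cluster gave 257 neutrophils and 170 cells named dendritic, and neutrophils made up 0.2505 ± 0.108, 0.486 ± 0.115 and 0.597 ± 0.330%. Cholangiocytes were few and uneven, with 0, 3 and 1 cells in control libraries A, B and C, 6, 31 and 1 at 2 weeks and 3, 41 and 27 at 4 weeks. None of these shares was tested between groups.

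Gpnmb, seen first in macrophages, was also higher in cells of the stellate class, with 1.19 ± 1.09 CPM in controls, 23.3 ± 10.4 at 2 weeks and 89.7 ± 37.0 at 4 weeks. Its log2 fold changes were 4.29 ± 0.83 and 6.24 ± 0.74 (edgeR adjusted p = 0.00904 and 0.000851), and 1.95 ± 0.42 between 4 and 2 weeks (adjusted p = 0.0325). Levels in macrophages of the 4-week libraries were 217 ± 119 CPM. The 2-week call ended without control C (3.61). The call between 4 and 2 weeks ended without 2-week B (1.77), 2-week C (1.79), 4-week A (1.68), 4-week C (1.94), control A (1.94) or control C (1.94). It also ended in a fit of 2 groups (1.94), with no filter on low counts (1.93), with the unnamed cluster (1.45) and in clusters 5 and 6 alone (0.36).

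Macrophages of 4-week library A differed from those of all other libraries in single abundant genes, none of which passed between groups. Cxcl13, a chemokine of B cell areas, had 3645 CPM there against 34.7 and 61.0 in 4-week B and C, 44.3 to 81.4 at 2 weeks and 349 to 637 in controls. Ccl24, an eosinophil chemokine, had 7.45 CPM against 219 and 280 in 4-week B and C, 314 to 456 at 2 weeks and 245 to 362 in controls. The scavenger receptor gene Marco had 2758 CPM against 423 and 332, with 424 to 683 at 2 weeks and 720 to 1630 in controls.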
